A study of Caenorhabditis elegans with 2 samples.

How the data were processed

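Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole *Caenorhabditis elegans* larvae of the L3 stage that carried a transgene for SNPC-4 fused to enhanced green fluorescent protein. SNPC-4 is a subunit of SNAPc, the small nuclear RNA activating protein complex, which binds promoters of small nuclear RNA genes. The labels give 2 biological replicates of 1 group. A control alignment is named per the file headers as an input of every list, and its values were not analysed here. The aligner, the peak caller, the threshold on the peak list and the extraction protocol are not given in the sources used here.

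The lists of regions were used as deposited. The authors deposited a thresholded list of 2672 peaks on the ce11 assembly, made from both replicates with the irreproducible discovery rate (IDR) method. They also deposited 1 list of regions for the pooled replicates and 1 for each replicate, each with 30000 regions that hold peaks and background together, per the file headers. The thresholded list on the ce10 assembly (2710 peaks) was used only for counts per chromosome. Each region has a signal value in an arbitrary unit on the scale of its own list, as the authors deposited it. It was used to rank and describe peaks within a list and never set across lists. Each region also has a −log10 q-value, as the authors deposited it. In the thresholded list this was the same for all peaks (3.88), so it was not used for ranking. The 2672 thresholded peaks on ce11 had the same positions as the 2672 strongest regions of the pooled list. The lists give no read counts, so the depth of each replicate is unknown, and no interval based on reads is given. Intervals of shares are exact binomial (Clopper-Pearson) intervals at 95% over genes or peaks. They cover counting error only, and neighbouring genes or peaks are not independent.

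Peaks were placed on the RefSeq annotation of WBcel235, the assembly that ce11 names. No region ended beyond a chromosome end. The annotation held 46890 nuclear genes. A peak's position was its summit. Each nuclear peak was assigned to the first class with an annotated 5′ end within 500 bp, in this order: spliced leader RNA, snRNA, RNase P, RNase MRP and Y RNA, tRNA, rRNA, snoRNA, miRNA, histone, ribosomal protein, other protein-coding, piRNA, other noncoding RNA and pseudogene. RNA genes of the signal recognition particle had been planned, by annotated type, as part of the RNase P, RNase MRP and Y RNA class. The annotation did not give them that type, so they fell under other noncoding RNA. Peaks on mitochondrial DNA were kept apart. The tests per class counted each class without this order. Further lists of protein-coding genes covered epidermal collagens, muscle, intestine, neurons, germline, sperm, heat shock, and SNAPc with 21U-RNA transcription factors, which gave 21 classes in all.

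The number of peaks within 500 bp of a 5′ end of a class was compared with circular shifts. All peaks of a chromosome were moved together by a random offset, in 10000 draws. The test was two-sided, and the smallest p it can give is 0.0002. A second comparison moved each peak on its own by 2000 to 20000 bp. Shares of genes with a peak were compared with those of protein-coding genes outside the class by Fisher's exact test. Peak strength was compared as the difference in median rank from peaks assigned to protein-coding genes, by a permutation test with 100000 draws. For the class with 3 peaks all possible triples were enumerated. For the 7 histone peaks enumeration was not feasible. Counts per chromosome were compared with the share of nuclear length by exact binomial tests. The piRNA clusters of chromosome IV were 100000-bp bins with at least 50 piRNA genes, adjoining bins joined, and were tested by circular shifts within the chromosome. Words of 8 bases were tested by exact McNemar tests between the 200 bp at the summit and 200 bp centred 600 bp away on a random side. All p-values of a family were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05.

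These tests, their alternatives and the gene lists were fixed before the data were examined. So was the rule for named genes: those at the 20 strongest peaks, up to 3 at the strongest peaks of each class, and every member of the spliced leader RNA, RNase P, RNase MRP and Y RNA, and SNAPc and 21U-RNA lists, with *unc-119*. An upstream element was learnt after the data were examined. One motif of 22 bp per gene was fitted by expectation maximisation to the sense strand 100 to 20 bp upstream of 50 spliced leader RNA and snRNA genes with a peak. A match was a score that 1% of 10000 random 200-bp windows of the nuclear genome reached. Those 50 genes are not independent evidence for it.

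The shift tests were tested on simulated data with 2646 peaks, 30 of them placed at snRNA genes. Both kinds of shift recovered snRNA genes in 100% of 100 simulations. They called 3% and 3.67% of class tests at an unadjusted p under 0.05 when no peak was placed. These simulated peaks were drawn independently and evenly over the chromosomes, so the rates do not cover clustered peaks. The permutation of ranks, the 8-base words and the element search recovered 99%, 100% and 100% of what was planted. With the 200 draws tried first, class tests could not pass the adjusted threshold, so 1000 draws per simulation were used. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

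Alternatives were other windows, the interval midpoint, whole intervals against gene bodies, the stronger 50% of the list, thinned peaks, other shift lengths, other overlaps, other bins and word lengths, and each replicate left out. With 1 replicate left out, the 2672 strongest regions of the other replicate's list took the place of the thresholded list. The lists of background regions on ce10 were left out because no ce10 annotation was used here, and no coordinates were converted between assemblies.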

Results

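The lists described where tagged SNPC-4 was found along the genome of L3 larvae, in 2 replicates of 1 group. There was no second condition, so bound positions were compared with the rest of the genome, between gene classes and between replicates. The thresholded list held 2672 peaks with a median width of 290 bp. Of these, 2646 lay on the nuclear chromosomes and 26 on mitochondrial DNA. The deposited signal value ran from 29.1 to 2235 with a median of 47.2. All coordinates are on ce11.

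Which genes tagged SNPC-4 bound most strongly was the first question. Small noncoding RNA genes held 16 of the 20 strongest peaks, counting spliced leader RNA, snRNA, RNase P, RNase MRP and Y RNA, tRNA and snoRNA genes together. They held 53 of the 100 strongest (53%) but 6.77% of those after the first 500. Mitochondrial DNA held 2 of the 20 strongest and 12 of the 100 strongest. The strongest peak (II, 15025767 to 15026179, signal 2235) had its summit 75 bp upstream of the snoRNA gene *Y53F4B.47* (signed position -75). The second (III, 10989420 to 10989835, signal 2125) lay at the snRNA gene *W05B2.8*, with the summit at -54. *F08G2.13*, a noncoding RNA gene of 75 bp with no further class, held the third (II, 13834383 to 13834792, signal 1879). The spliced leader genes *sls-2.8* (III, 12250236 to 12250614, signal 1838) and *sls-2.4* (I, 4171967 to 4172547, signal 1786) followed. Other snRNA genes among the 20 strongest were *F38E11.10* (signal 1572), *C52E4.8* (1324), *sup-6* (1269) and *smy-1* (1130). The summit at *smy-1* lay at 305 bp, downstream of this 77-bp gene, unlike those of the other 3, and a weaker peak (signal 61.0) had its summit at -96 bp. The snoRNA genes *ZK994.7* (1756), *F59C6.15* (1255), *C16D9.11* (1192), *Y37E3.20* (1009), *C08D8.3* (1000.4) and *F01D5.12* (988) were also there. *mir-2214* (III, 7278452 to 7278821, signal 1029) was the only microRNA gene among them. No protein-coding gene was assigned to any of the 20.

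Spliced leader RNAs supply the short leader that nematodes join to the start of many messenger RNAs. The SL2 genes (*sls-2*) had a peak at 17 of 19 members. The strongest peak in the window of *sls-2.15* was that of *sls-2.14*, with the summit at -429 bp from *sls-2.15* and -58 bp from *sls-2.14*. The SL2 genes with the strongest peaks after *sls-2.8* and *sls-2.4* were *sls-2.2* (signal 1359), *sls-2.1* (1255) and *sls-2.3* (616). The weakest peak was that at *sls-2.19* (32.7). *sls-2.12* and *sls-2.11* had none, but each had a pooled region below the threshold (rank 14447 with signal 9.04, and rank 2910 with signal 27.2). None of the 12 SL1 genes (*sls-1*), which lie between 17118154 and 17132107 on V, had a peak. None had a pooled region either. A median of 0% of the sequence around their annotated start was unique, so reads shared between copies may account for this. The RNA subunit genes of 2 ribonucleases that process other RNAs, *rpr-1* of RNase P (I, 13463757 to 13464104, signal 959) and *mrpr-1* of RNase MRP (II, 7200048 to 7200357, signal 763), both had strong peaks. The Y RNA gene *yrn-1* had a weaker one (IV, 7499326 to 7499615, signal 56.8). The signal recognition particle RNA genes *srpr-1.1*, *srpr-1.2*, *srpr-2.1*, *srpr-2.2* and *srpr-3*, counted with other noncoding RNA, had no peak. They were picked by name after the annotation was seen. Each had a pooled region below the threshold, the strongest at *srpr-1.1* (rank 2781, signal 28.3).

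Peaks lay near small RNA genes far more often than shifted peaks did. They lay within 500 bp of a spliced leader 5′ end 18 times, against 0.769 ± 0.914 (SD over shifts) after circular shifts, a 23.4-fold excess. For snRNA genes the count was 34, or 14.4-fold, and for RNase P, RNase MRP and Y RNA it was 3, or 33.6-fold. The excess was 9.78-fold at snoRNA genes (89 peaks), 7.05-fold at tRNA genes (97 peaks) and 4.57-fold at microRNA genes (28 peaks). Ribosomal protein genes had 57 peaks (25.5-fold) and the heat shock list 5 (21.1-fold). Other protein-coding genes had 1341 peaks (2.73-fold) and other noncoding RNA genes 486 (2.99-fold). Of those 486 peaks, 190 were assigned to other noncoding RNA, as the rest also lay near a class earlier in the order. Each class named so far in this paragraph had a Benjamini-Hochberg adjusted p of 0.0014 or less by the permutation of positions. The adjusted p of 0.00042 is the smallest these draws gave. Histone genes had 7 peaks (5.70-fold, permutation adjusted p = 0.00258). Peaks were fewer than after shifts at piRNA genes (78 peaks, 0.625-fold) and pseudogenes (20 peaks, 0.387-fold), both with an adjusted p of 0.00042 by permutation. No rRNA gene had a peak, where 0.440 were expected. At 15 of 20 rRNA genes most of the sequence around the 5′ end was not unique, so reads shared between copies may account for part of this.

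The same 13 of 21 classes passed when each peak was moved on its own by 2000 to 20000 bp. The folds were then 24.1 at spliced leader genes, 10.4 at snRNA genes, 6.79 at snoRNA genes, 6.31 at tRNA genes and 19.5 at ribosomal protein genes. They were lower at RNase P, RNase MRP and Y RNA genes (15.8, against 33.6) and at histone genes (3.26, against 5.70). With moves of 1000 to 5000 bp the former had no fold, as the expected count was 0, and that at snRNA genes was 6.98. The histone excess did not pass without replicate 2 (3.23-fold, permutation adjusted p = 0.144) or in the stronger 50% of the list (4.94-fold, adjusted p = 0.0911). With whole intervals counted over gene bodies with 500 bp upstream, in place of summits near 5′ ends, other protein-coding genes were at 1.01-fold (permutation adjusted p = 0.721). The deficit at pseudogenes did not pass with moves of 1000 to 5000 bp (0.824-fold, permutation adjusted p = 0.651). The size of the folds depended on the window. At 250 bp and at 1000 bp they were 44.9 and 14.4 at spliced leader genes, 27.5 and 8.15 at snRNA genes, 66.1 and 17.3 at RNase P, RNase MRP and Y RNA genes, and 12.8 and 4.27 at tRNA genes. At ribosomal protein genes they were 13.4 and 14.2. In the stronger 50% of the list the folds were 42.5 at spliced leader genes, 23.3 at snRNA genes and 43.8 at ribosomal protein genes. At the heat shock list the fold was 13.4 at 1000 bp, 10.1 over gene bodies and 8.45 with moves of 1000 to 5000 bp. At 250 bp the folds were 16.6 at snoRNA genes, 9.68 at histone genes and 4.51 at other noncoding RNA genes, and at 1000 bp that of microRNA genes was 3.01.

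Not every member of a class had a peak. The share was 54.8% of 31 spliced leader genes (95% interval 36.0 to 72.7), 33.3% of 99 snRNA genes (24.2 to 43.5) and 25.7% of 346 snoRNA genes (21.2 to 30.7). It was 17.6% of 612 tRNA genes (14.7 to 20.9) and 75.6% of 78 ribosomal protein genes (64.6 to 84.7). Protein-coding genes had a peak in 8.94% (1785 of 19971). Fisher's exact test separated all of these classes from protein-coding genes, the largest adjusted p being 3.22e-10. The share of spliced leader genes mixed genes with and without unique sequence around the 5′ end, as described among the flagged results. Of 18 with at least 50% unique sequence there, 17 had a peak (94.4%), against 0 of the other 13. In the stronger 50% of the list the share of tRNA genes did not pass (Fisher's exact test, adjusted p = 0.294). With a window of 250 bp the excess of the share at ribosomal protein genes over other protein-coding genes was 13.5 percentage points, against 67.0. Histone genes at 16.7% (12 of 72) did not pass Fisher's exact test (adjusted p = 0.0558), nor did microRNA genes at 11.5% (30 of 260, adjusted p = 0.216). The excess at histone genes was 7.76 points. It was 10.9 points at 250 bp (exact, adjusted p = 0.00164), 1.12 points without replicate 2 (0.744) and 1.70 points in the stronger 50% of the list (0.635). Only 1.18% of 15363 piRNA genes and 0.939% of 2130 pseudogenes had a peak, both lower than protein-coding genes by Fisher's exact test (adjusted p = 4.97e-258 and 2.37e-54). Other noncoding RNA genes, at 7.70% (620 of 8055), were lower as well (adjusted p = 0.00158, exact), but not at 250 bp, where the difference was 0.222 points (adjusted p = 0.693).

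**Figure D1:**
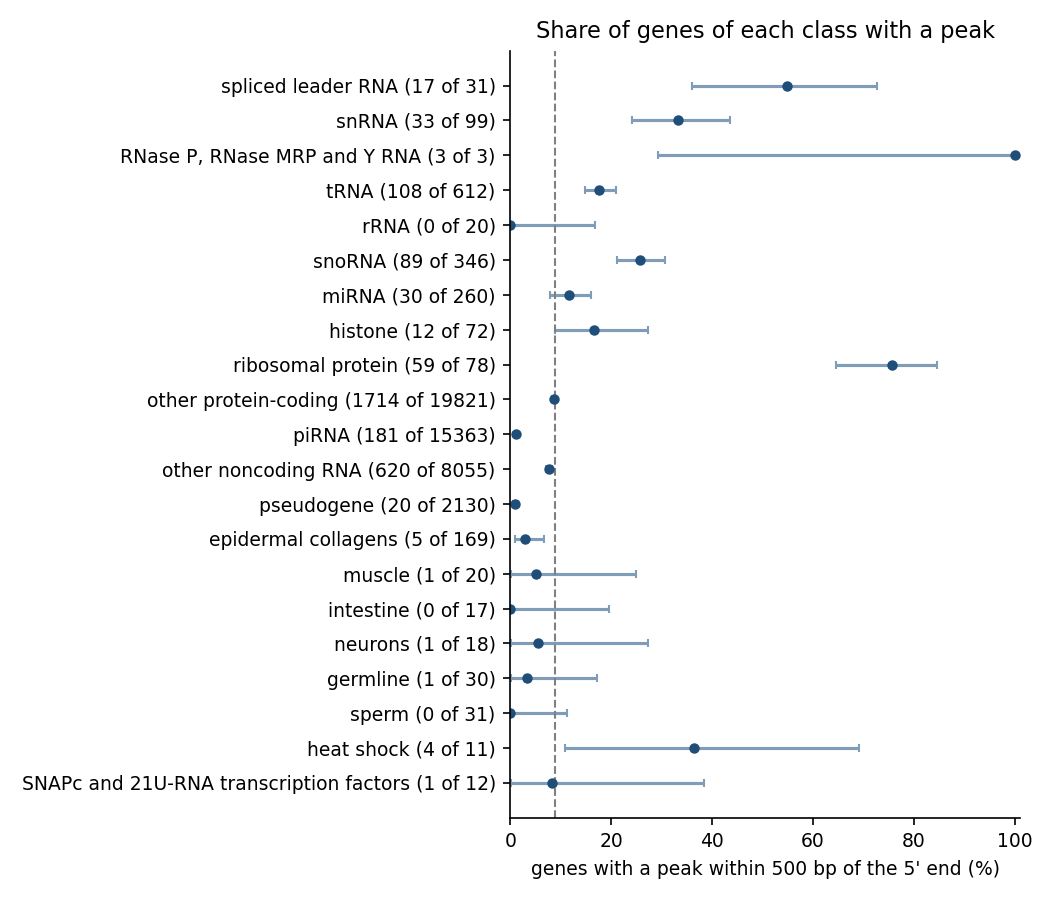
Share of genes of each class with a peak summit within 500 bp of the annotated 5′ end (x axis, %), with exact 95% binomial intervals; the dashed line is the share of all protein-coding genes, 8.94%. RNase P, RNase MRP and Y RNA genes (3 of 3), ribosomal protein genes (75.6%) and spliced leader genes (54.8%) lie farthest to the right. The class of 3 holds no RNA gene of the signal recognition particle.

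Tissue lists were not separated from shifted peaks, but most were too small for this test to call a deficit. Shifted peaks gave 4.36 near collagens. Near the muscle, intestine, neuron, germline and sperm lists they gave from 0.415 (intestine) to 0.827 (sperm). Epidermal collagens, which build the cuticle, had 5 of 169 genes with a peak (*col-71*, *col-72*, *col-38*, *col-85* and *col-2*), a 1.15-fold count with an adjusted p of 1 by circular shifts. Their share of 2.96% was below that of protein-coding genes by Fisher's exact test (adjusted p = 0.00758), which did not pass in the stronger 50% of the list (adjusted p = 0.0702). One gene each had a peak in the muscle list (*act-2* of 20), the neuron list (*snb-1* of 18) and the germline list (*nos-3* of 30). No gene of the intestine list (17) or the sperm list (31) had one. All 6 lists had an adjusted p of 1 by circular shifts. The heat shock list had peaks at 4 of 11 genes. These were *hsp-90* (signal 115), *hsp-1* (75.1), *hsp-3* (53.4) and *hsp-70* (30.03), which encode chaperones. The peak counted for *hsp-90* lay nearer to the 5′ end of *C47E8.4* (summit at -266 bp, against -409 bp from *hsp-90*), and a weaker peak (signal 30.06) was assigned to *hsp-90* itself, with the summit at 163 bp. The stress-induced *hsp-16* genes of the list, *hsp-16.1*, *hsp-16.2*, *hsp-16.41*, *hsp-16.48* and *hsp-16.49*, had none, nor did *hsp-4* and *hsf-1*. Part of this contrast rests on the threshold. *hsp-4* had the pooled region just below it (rank 2673, signal 29.07), and *hsp-16.2* and *hsp-16.41* shared one of rank 3047 (signal 26.2). The peak at *hsp-70* passed at rank 2585, but ranked 5661 in the replicate 1 list. *hsp-16.1*, *hsp-16.48*, *hsp-16.49* and *hsf-1* had no pooled region in the window either. With a window of 250 bp the share of heat shock genes did not pass Fisher's exact test (adjusted p = 0.230).

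Among the genes for SNAPc and for transcription factors of 21U-RNAs (the piRNAs of *C. elegans*), only *snpc-3.4* had a peak (III, signal 49.6, summit at -15). The other 11, which include *snpc-4* itself, *prde-1*, *tofu-4*, *tofu-5*, *unc-130* and *tbp-1*, had none within 500 bp. The list did not pass the permutation of positions (adjusted p = 0.856). *unc-119*, named in the genotype of the strain, had none either.

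Peak strength followed gene class. The median rank was 72.5 at 18 spliced leader peaks and 346.5 at 34 snRNA peaks, against 1170.5 at peaks assigned to protein-coding genes (permutation test, adjusted p = 8.67e-05 and 0.000286). It was 612 at 87 snoRNA peaks (permutation adjusted p = 8.67e-05). At 96 tRNA peaks it was 1737.5, weaker than at protein-coding genes (permutation adjusted p = 0.00013). The 50 ribosomal protein peaks had a median rank of 561.5 against 1197 at the other protein-coding peaks (permutation adjusted p = 0.000873). In the replicate 1 list alone this difference fell to -383.5 ranks and did not pass the permutation test (adjusted p = 0.0818). The 3 peaks at RNase P, RNase MRP and Y RNA genes (median rank 28) passed in the thresholded list by an exact permutation test (adjusted p = 0.0427), but in neither replicate list alone (adjusted p = 0.139 in replicate 1 and 0.154 in replicate 2). Other noncoding RNA peaks were weaker than protein-coding ones by 227 ranks (permutation adjusted p = 0.0259), which did not pass in the replicate 1 list (44.5 ranks, 0.745) or the replicate 2 list (69.5 ranks, 0.547).

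Summit positions relative to the annotated 5′ end differed between classes. The median summit lay at -54 bp from the annotated 5′ end at spliced leader genes, -53.5 bp at snRNA genes and -51 bp at snoRNA genes. Between 30 and 80 bp upstream lay 15 of 18 spliced leader peaks (83.3%), 29 of 34 snRNA peaks (85.3%) and 43 of 87 snoRNA peaks (49.4%). At tRNA genes the median was -23 bp, with quartiles of -38.25 and 23.25 bp. At ribosomal protein genes it was -307 bp and at other protein-coding genes -158 bp.

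**Figure D2:**
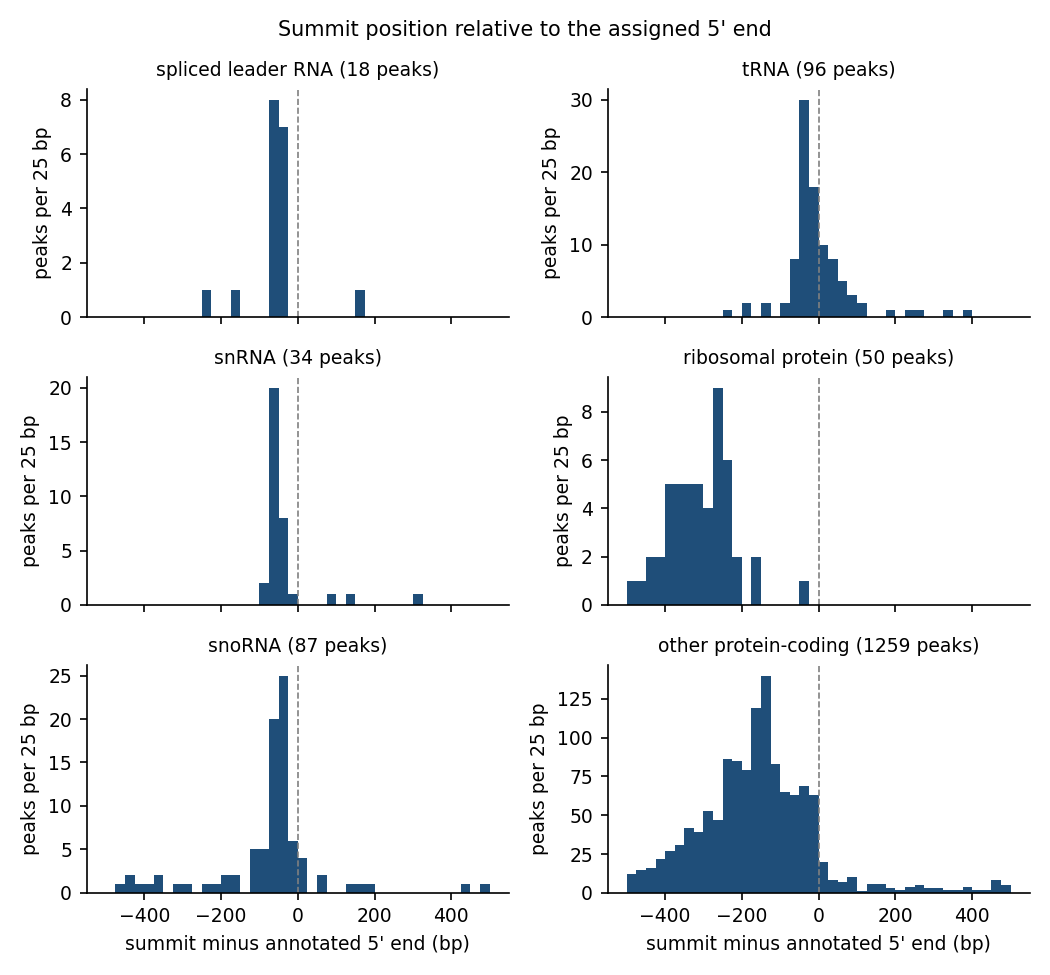
Number of peaks per 25 bp (y axis) by position of the summit relative to the annotated 5′ end of the assigned gene (x axis, bp; negative is upstream; dashed line, the 5′ end), for 6 classes. Spliced leader, snRNA and snoRNA peaks pile up near -50 bp, tRNA peaks at the 5′ end and ribosomal protein peaks around -307 bp.

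An element of 22 bp, with GCGGAACCCGCGAGATGTCGGT as its most frequent bases, was fitted upstream of 50 spliced leader and snRNA genes with a peak, with 1 occurrence assumed per gene. By its score, 15 of 18 spliced leader and 29 of 34 snRNA peaks had a match. The fitted occurrences began at a median of -63 bp (quartiles -63 and -62). It was found at the summit of 34 of 87 snoRNA peaks (39.1%) and in none of their flanks 600 bp away (exact McNemar test, adjusted p = 6.6e-10). Those 34 peaks had a median signal of 579, against 45.7 at the 53 snoRNA peaks without it (permutation of ranks, adjusted p = 3e-05). All 3 peaks at RNase P, RNase MRP and Y RNA genes had it. Of 96 tRNA peaks 2 had it, the same number as in the flanks. No ribosomal protein peak of 50 had it. It was found at 7 of 34 peaks assigned to piRNA genes (20.6%) and in 0 flanks (exact McNemar test, adjusted p = 0.0295), and at 13 of 190 other noncoding RNA peaks and in 2 flanks (adjusted p = 0.0157). The summits of those 34 peaks lay at a median of 161 bp from the piRNA 5′ end, and 0 lay 30 to 80 bp upstream. These matches therefore do not place the element upstream of piRNA genes as at snRNA genes. Peaks with no annotated 5′ end within 500 bp had the element at 15.6%. Among 1259 peaks at other protein-coding genes the element was found at 33 (2.62%), against 9 flanks (exact McNemar test, adjusted p = 0.000516). It was present at 40 of the 47 nuclear peaks among the 50 strongest (85.1%) and at 166 of the 2171 after the first 500 (7.65%). These counts include peaks at the genes the element was fitted on, so they are not independent evidence that it goes with strength.

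**Figure D3:**
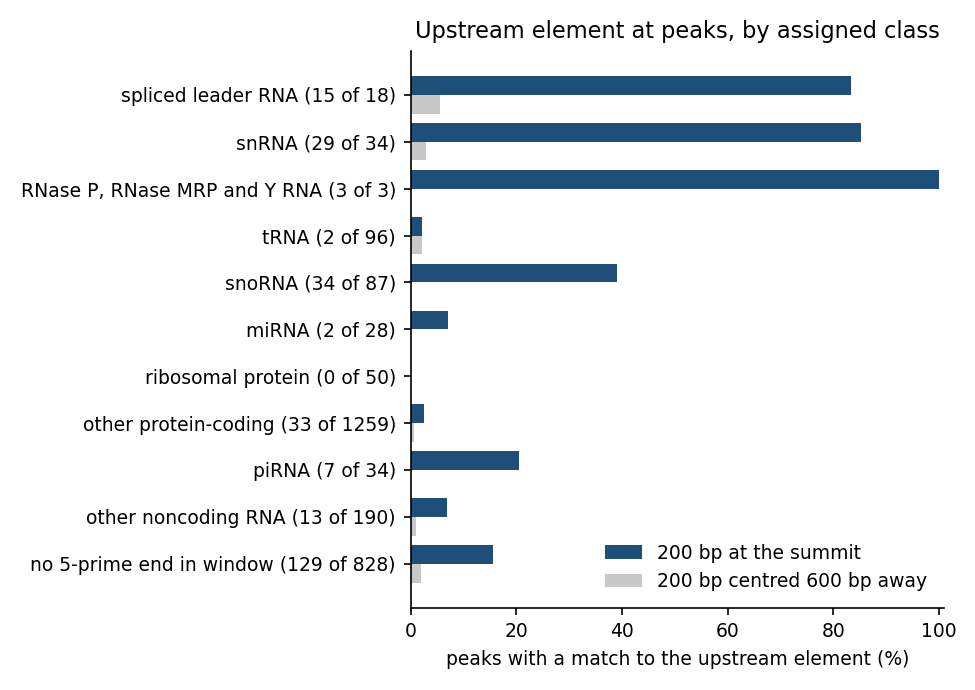
Share of peaks (x axis, %) with a match to the upstream element in the 200 bp at the summit (dark bars) and in 200 bp centred 600 bp away (grey bars), by assigned class; the number of peaks with a match stands beside each class. The element was fitted on spliced leader and snRNA genes and was seen at 39.1% of snoRNA peaks and 2.08% of tRNA peaks.

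Sequence words were tested at all 2646 nuclear peaks. The 8-base word with the lowest p was AGACGCAG, present at the summit of 410 peaks and in 33 flanks (exact McNemar test, adjusted p = 3.53e-83). GAGAGAGA was present at 320 peaks and 35 flanks (exact adjusted p = 1.69e-56), and CACACACA at 215 peaks and 25 flanks (1.85e-39). In all, 2665 of 16903 words tested were more frequent at the summit and 1186 less frequent. Among the latter, AAAAATTT was present at 156 peaks and 412 flanks. Without the peaks near tRNA genes, AGACGCAG was again first (408 of 2549 peaks against 32 flanks).

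piRNA genes are dense in parts of chromosome IV, where SNPC-4 is known from the literature to act in the germ line. Clusters were defined there, at 4800001 to 6300000, 6400001 to 6600000 and 13600001 to 17300000, with 14124 of the 14714 piRNA genes of the chromosome. They held 139 of the 452 thresholded peaks on IV, against 139.5 ± 11.5 (SD) after shifts (0.996-fold, p = 0.943 by permutation). The word CTGTTTCA, known from upstream of 21U-RNA genes, was present at 14 of 2646 peaks (0.529%) and in 38 flanks (1.44%), so it was less frequent at summits (exact McNemar test, adjusted p = 0.0167). The exact test did not pass with windows of 100 bp (adjusted p = 0.0521) or 400 bp (adjusted p = 0.270). No single class passed. Of the 34 peaks assigned to piRNA genes 1 had the word, and 7 flanks did (exact McNemar test, adjusted p = 0.492). These comparisons cover thresholded peaks only. Of pooled regions below the threshold 13.3% lay in the clusters, against 5.20% of the thresholded peaks. Of those in the clusters, 28.6% had the word at the summit and 20.7% in the flank, as described among the flagged results.

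Peaks were spread over all chromosomes. Density was highest on III, with 31.8 peaks per Mb (1.21-fold of its share of nuclear length, exact binomial test, adjusted p = 9.86e-05), and on I, with 30.3 per Mb (1.15-fold, adjusted p = 0.00319). It was lowest on V, with 20.2 per Mb (0.764-fold, exact binomial, adjusted p = 9.46e-10). II had 29.1 per Mb (exact binomial, adjusted p = 0.0427), which did not pass after peaks within 5 kb were merged (adjusted p = 0.154). IV (0.979-fold) and X (0.924-fold) did not pass. On X the 0.907-fold count without replicate 2 did (exact binomial, adjusted p = 0.0319).

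The replicates were compared at the same number of regions. Of the 2672 strongest regions of replicate 1, 1810 overlapped one of the 2672 strongest of replicate 2 by at least 1 bp (67.7%, 95% interval 65.9 to 69.5). After circular shifts the mean share was 2.25% and the highest 3.14%. Of the thresholded peaks, 2647 overlapped a region in both replicate lists, and 1766 (66.1%) one of the 2672 strongest in both. Across those 2647 peaks the ranks in both lists had a Spearman rho of 0.546 (bootstrap interval 0.515 to 0.577). Peaks are not independent replicates, so no p is given. Agreement was closest at spliced leader peaks (rho 0.961, 17 peaks), snRNA peaks (0.913, 34 peaks) and snoRNA peaks (0.867, 87 peaks). It was 0.550 at other protein-coding genes, 0.408 at tRNA genes and 0.349 at peaks with no annotated 5′ end within 500 bp.

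**Figure D4:**
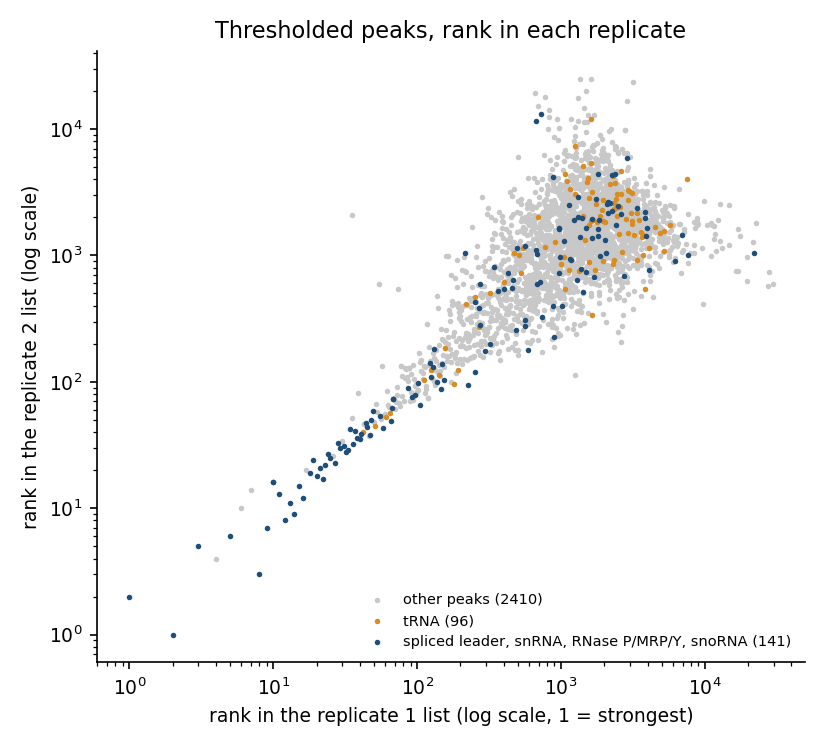
Rank of each thresholded peak in the replicate 1 list (x axis) and in the replicate 2 list (y axis), both on log scales with 1 the strongest; 1 point is 1 of the 2647 peaks with a region in both lists. Small RNA genes other than tRNA genes (dark) fill the strong end, where the ranks lie close to each other, and the scatter widens among weaker peaks.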

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

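Only the separate tests of the element at ribosomal protein and at heat shock peaks were chosen after the result was seen, but the peaks at ribosomal protein and heat shock genes had been seen before their tests were written, and how to read 2 tests was settled after their values were known: that of the 21U-RNA word against a regional rise, and that of the list threshold. For these 2, and for the replicates of the promoter peaks, the bounds written in advance for excluding an explanation were not reached. What the 21U-RNA word argues against is only a regional rise as the whole cause. The tests of the list threshold and of the replicates of the promoter peaks exclude nothing.

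Pooled regions below the threshold, which the report's tests by gene class, chromosome and sequence leave out, were concentrated in the piRNA gene clusters of chromosome IV. The clusters held 3648 of 27328 such pooled regions (13.3%), against 5.20% of the thresholded peaks. Base composition does not account for it, since the number was 2.30 times that in windows of equal GC content elsewhere on the chromosome (block bootstrap interval 2.09 to 2.51), nor does noise of 1 replicate, since the share was 2.09 times that of the thresholded peaks in replicate 1 and 2.30 times in replicate 2. A regional rise in background as the whole cause is argued against by the word CTGTTTCA, found at 28.6% of these summits and 20.7% of flanks, a ratio of 1.39 (interval 1.29 to 1.501, exact McNemar p = 1.14e-15), against 0.930 elsewhere; the ratio was above the 1.2 such a rise allows but under the 1.5 set in advance, so a regional share of the rise stays open. No biological explanation was tested for this pattern.

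Peaks at ribosomal protein and heat shock genes formed a second pattern. The upstream element of snRNA genes does not account for the 50 ribosomal protein peaks, since 0% had it (upper bound 7.11%), against 39.1% at snoRNA genes, but for the 5 heat shock peaks it stays open, since 1 had it (20%, interval 0.505 to 71.6, at *hsp-3*). Measured from the annotated 5′ end, the summits were not placed as at snRNA genes. Of all 55, 0% lay 30 to 80 bp upstream (upper bound 6.49%), and the median was -309 bp. No start of transcription was mapped here, so placement relative to the true start was not tested. Of these peaks 85.5% lay among the 2672 strongest regions of both replicates (interval 73.3 to 93.5, with 44 of 50 and 3 of 5). This was short of the 90% set in advance, and the share over all thresholded peaks was 66.1%. The thresholded list was itself made from both replicates with the IDR method. Presence in both was therefore partly fixed by that choice, and the share does not decide on noise of 1 replicate. Open chromatin as a source of signal was not tested, as no other factor was analysed, and no biological explanation was tested.

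Many small RNA genes had no peak. Reads shared between near-identical copies may account for part: of spliced leader, snRNA and rRNA genes with under 50% of their 32-base words around the 5′ end unique, 9.43% had a peak (5 of 53), against 46.4% of the others (45 of 97, Fisher's exact p = 1.91e-06), though for snRNA genes alone the shares were 20% and 37.8% (exact p = 0.141). The 12 SL1 genes had a median of 0% unique words and the 19 SL2 genes 90.7%. At tRNA genes shared reads leave most of the pattern open, since 5.16% of the 504 without a peak had so little unique sequence, although none of those 26 genes had a peak, against 18.4% of the others (Fisher's exact p = 0.00804). Of these 504 tRNA genes, 304 had a pooled region below the threshold in the window, as had 92 of 257 snoRNA genes without a peak. The list threshold may therefore account for part of them, though the pooled list holds peaks and background together. Of the 80 spliced leader and snRNA genes without a peak, 35% had a pooled region below the threshold (interval 24.7 to 46.5). This was above the 25% set in advance. The pooled list is itself limited in length, so signal weaker than its last region is not seen. The share therefore does not decide how many of these genes the list threshold accounts for. No biological explanation was tested for this pattern.

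Mitochondrial DNA, which the comparisons by gene class leave out, held 26 thresholded peaks. They covered 66.6% of its 13794 bp, and its length alone would give 0.368 peaks. The figure from length takes no account of the copy number of this DNA, which was not measured, and the control was not analysed. Of these peaks 25 lay among the strongest regions of both replicates, at the size of the thresholded list. Ranks in both lists had a Spearman rho of 0.121 (25 peaks, bootstrap interval -0.404 to 0.602). Whether these peaks reflect binding of tagged SNPC-4 was not tested.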

How the results depend on the processing

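All alternatives of this part were planned, and no test was chosen after its result was seen. Of 482 alternative values, 425 kept their direction and their side of the threshold (or, with no test, stayed within their spread), 30 turned direction, 17 no longer passed, 3 newly passed and 7 counts or shares moved. The cause was not tested for any of these. No called value turned direction except the share at other noncoding RNA genes. The midpoint of the interval, peaks thinned to 1 kb, flanks 2000 bp away, other piRNA bins and the ce10 list, which was set against ce11 chromosome lengths, changed no call. The planned use of the strongest pooled regions could change nothing, as 2672 of 2672 positions were those of the thresholded list. Local moves of 1000 to 5000 bp gave no fold at RNase P, RNase MRP and Y RNA genes, since no moved peak fell near them (expected 0), and the 21U-RNA word was recomputed only for classes with at least 10 peaks. No paired analysis was possible because there is 1 group. What depth limits is unknown, as the lists give no read counts.

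With a window of 250 bp the folds were 0.460 at collagens, 0 at the muscle list and 0 at the neuron list, and the differences in share were -0.823 points at microRNA, 10.9 at histone, 0.222 at other noncoding RNA, 12.4 at heat shock and 2.51 at SNAPc and 21U-RNA factor genes. With 1000 bp the folds were 0.814 at collagens, 0.615 at the germline list and 1.23 at the sperm list. Over gene bodies they were 1.01 at other protein-coding genes, 0.594 at muscle, 0.948 at neurons, 0.3202 at germline and 0.853 at SNAPc and 21U-RNA factor genes. In the stronger 50% of the list they were 4.94 at histone and 0 at neuron genes, and the differences in share 1.29 points at tRNA, -3.50 at collagen and 3.09 at SNAPc and 21U-RNA factor genes. Local moves of 1000 to 5000 bp gave 0.824 at pseudogenes and 0.870 at neurons. The replicate overlap was 62.6% with at least 50% of each region shared and 61.1% at 5000 regions. Merged peaks gave 1.08 on II. The word CTGTTTCA passed in 0 classes, counting all peaks as one, with 100 bp (-0.605 points) and in 0 with 400 bp (-1.02 points). Of words of 7 bases, 1742 were enriched.

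With each replicate left out, the folds ran from 3.23 to 5.67 at histone genes, 0.917 to 1.14 at collagens, 0 to 2.38 at intestine and 0 to 3.97 at neurons. Against local moves they ran from 2.05 to 3.78 at histone genes, 0.966 to 1.29 at collagens, 0 to 2.72 at intestine and 0 to 4.16 at neurons. Differences in share ran from -3.61 to 1.17 points at muscle, -8.84 to 2.51 at neurons and -0.274 to 7.84 at SNAPc and 21U-RNA factor genes. Differences in rank ran from -1249 to -1185 at RNase P, RNase MRP and Y RNA, -648.5 to 103 at histone, -795 to -383.5 at ribosomal protein, 329.5 to 785.5 at other protein-coding and 44.5 to 69.5 at other noncoding RNA genes, with 5 to 7 classes passing. Chromosome IV ran from 0.982 to 1.01 and X from 0.907 to 0.954, and the piRNA clusters from 1.00 to 1.08. The word CTGTTTCA passed in 1 to 2 classes, and at peaks with no gene its difference ran from -1.43 to 0.118 points.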

Other observations

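Of the tests in this part, those on the stretch around *snpc-4*, on tRNA genes of the X chromosome, and on the presence of the element and the strength of peaks with it were chosen only after the result was seen, as were the genes named for them.

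The strongest tRNA peaks were at *C27A2.t1* (isoleucine, signal 551), *K11H12.t1* (selenocysteine, signal 488) and *ZC412.t1* (phenylalanine, signal 439). *K11H12.t1*, the only selenocysteine tRNA gene annotated, had the upstream element and its summit at -68 bp. On X 36 of 276 tRNA genes had a peak (13.04%), against 72 of 336 on the autosomes (21.4%; odds ratio 0.55, Fisher's exact p = 0.00761). The strongest ribosomal protein peaks were at *rpl-15* (signal 451), *rpl-18A* (412) and *rpl-3* (409).

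No annotated 5′ end lay within 500 bp of 828 thresholded peaks. The strongest (III, 11463830 to 11464167 on ce11, signal 863) lay inside *bed-2* and had the upstream element. The element was found at 129 of these peaks (15.6%) and in 17 flanks (exact McNemar test, adjusted p = 1.06e-24). One hypothesis is that some are promoters of small RNA genes that are not annotated. It predicts the element at the summit, and 69.0% of the matches were centred within 25 bp of it (interval 60.3 to 76.8), where an even spread would give 28.5%. A bound element would lie at the summit at other kinds of sites too, so this does not tell promoters from other bound sites. Peaks with the element were not detectably stronger than those without (median signal 44.4 and 41.9, permutation of ranks, adjusted p = 0.127), whereas those at snoRNA genes and at other protein-coding genes were (median rank 728 against 1208 at the latter, permutation adjusted p = 0.0383), and no transcript was measured. The hypothesis stays open.

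Of the 100 strongest peaks with no annotated 5′ end in the window, 35 lay on X (35%, interval 25.7 to 45.2), which makes up 17.7% of the nuclear genome. Of all 828 such peaks 23.1% did (20.2 to 26.1). This concentration had been seen before its test was written. A hypothesis is that some are recruitment sites of the dosage compensation complex, whose known motif holds the core GCGCAGGG. The core was found at 37.1% of those X peaks (13 of 35, interval 21.5 to 55.1), in 0 of their flanks and at 0 of 65 autosomal ones (Fisher's exact p = 2.08e-07). The other X peaks are not covered by it.

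No pooled region lay within 500 bp of the 5′ end of *snpc-4*, whose product the transgene encodes. The stretch of the pooled list without a region there ran over 43122 bp (I, 8944055 to 8987176 on ce11), and 4.599% of protein-coding genes had their 5′ end in a stretch at least as long. In replicate 1 the share was 2.30%, and in replicate 2, where the stretch began at 8962258, just before the gene, it was 9.24%. Extra copies of this part of the genome in the strain, which would raise the control as well, are a possible explanation that these values do not decide. At *unc-119*, the marker named in the genotype, the share was 63.1%. The control was not analysed.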
